A study of Mus musculus with 18 samples.

How the data were processed

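The series measured total RNA of sorted mouse naive CD4 T cells on arrays of the type Affymetrix 430 2.0 for mouse. The 18 arrays fall into 6 groups of 3, WT and STAT3-deficient cells kept for 3 hours in medium alone, with IL-6 or with IL-27. Per the labels, the authors made the values with GCOS, whose version, summarisation algorithm, genome build and annotation are not given in the sources used here. The deposited values are intensity, a linear probe set signal, which was checked on the values: all lie above 0, and the mean after trimming 2% at each end is 500.0 on every array. No array is identical to another.

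The table holds 45101 probe sets. The 64 control probe sets were left out, except for the hybridization controls in a check of how the arrays were processed. Of the others, 34945 had a single gene symbol, for 18193 genes, 932 had several and 9160 had none in the annotation used here. A gene table was used only for the order of genes along the chromosome of Stat3, and no genome came with it.

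Signals were transformed as log2 of the signal plus 32. The medians of the arrays differed by 1.82-fold, above the preset limit of 1.5, for which the plan called for quantile normalisation with limma (version 3.58.1, R 4.3.3), which also sets the scale of the changes reported. A probe set was kept where it lay above the median of its own array on at least 3 arrays, which left 26860. Each gene was read from its probe set with the highest mean, which gave 11971 genes. The added constant shrinks changes of weakly expressed genes. For arrays only their number limits the precision that can be stated.

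A limma model with a mean for each group was fitted to all 18 arrays (12 residual degrees of freedom, empirical Bayes with a trend of variance on mean, 6.25 prior degrees of freedom). There were 9 comparisons: each cytokine against medium and IL-27 against IL-6 in each genotype, the difference between genotypes in the IL-6 and in the IL-27 effect as interaction terms, and STAT3-deficient against WT cells in medium. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the genes tested in each comparison, and a gene was called at an adjusted p under 0.05. The median SE was 0.185 for a comparison of groups and 0.261 for an interaction. On simulated data with 200 changed genes, 37.0%, 70.2% and 95.5% of changes of 1.5-fold, 2-fold and 4-fold were called in a comparison of groups, and 5.27% of the calls were false.

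The choice of genes to name was fixed before the data were examined, as were the gene lists, the comparisons and all alternatives except those stated otherwise. Named genes are up to 8 per direction with the largest changes among called genes whose 3 arrays of one group lie beyond all 3 of the other (chance gives this for 10% of genes; interactions needed the call only), a fixed set of cytokine and T cell genes, and up to 4 members of each list. Cd3e, Cd74, Irf2, Irf9 and the second probe sets were chosen after their values were seen. The 23 gene lists, taken from textbook knowledge, are antiviral interferon-stimulated genes, interferon-inducible GTPases, MHC class I and antigen processing, JAK-STAT pathway and feedback, reported STAT3 targets, the Th17, Th1, Th2 and follicular helper programs, regulatory T cell and IL-10 genes, co-inhibitory and co-stimulatory molecules, naive and homing genes, T cell activation and immediate early genes, apoptosis regulators, chemokine and cytokine receptors, glycolysis, cell cycle, ribosomal proteins, heat shock and stress, and markers of B cells, of myeloid cells, of CD8 T and NK cells and of red blood cells.

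Lists with at least 5 measured genes, 22 in all, were tested with camera from limma at a preset correlation between genes of 0.01, two-sided, adjusted over the lists within a comparison, and again with an estimated correlation. Calls keep an adjusted p under 0.05 with an estimated correlation unless a p of 0.05 or more is given beside them. The estimated correlations were 0.194 for the antiviral list, 0.357 for the GTPases and 0.112 for the reported STAT3 targets, above the preset 0.01. The p-values at the preset correlation are therefore far too small for such lists, and their size does not measure certainty. Only genes with a probe set for that symbol alone were analysed, so several well-known genes of these pathways are not analysed here.

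Alternatives were the deposited scaling, median centring, other added constants and filters, the mean of all probe sets of a gene, no variance trend, array weights, only the arrays compared, a 2-fold minimum, blocks by the number in the sample names, and leaving out each array in turn. The numbers of the samples are not explained by the labels. After seeing the data, 2 alternatives were added: without the STAT3-deficient arrays numbered 3, and with the mean signal of B cell and myeloid markers as a covariate. Overlaps of calls were set against the product of their shares, and correlations across genes of comparisons with shared controls against 100 simulations. Figures were drawn with matplotlib 3.10.9.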

Results

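Gene expression was measured on 18 arrays of mouse naive CD4 T cells, sorted as CD44-negative, CD62L-positive and CD25-negative cells from spleen and lymph nodes. The cells came from wild type (WT) mice or from STAT3-deficient mice, in which Cd4-Cre removes Stat3 from T cells. They were kept for 3 hours in medium alone, with interleukin 6 (IL-6) at 20 ng/ml or with interleukin 27 (IL-27) at 20 ng/ml, and each of the 6 groups held 3 arrays, described in the series as biological triplicates. IL-6 and IL-27 both signal through the receptor chain encoded by Il6st. After filtering, 11971 genes were tested. The median signal of an array lay between 104.4 and 190.3 units as deposited, and the number of arrays limits the precision. The first principal component held 33.1% of the variance and separated all 9 WT arrays from all 9 STAT3-deficient arrays. Changes are given below as log2 values with the standard error (SE) of the limma model, for 3 arrays per group.

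The deleted gene comes first. In medium, Stat3, the transcription factor downstream of the IL-6 receptor, was lower in STAT3-deficient than in WT cells by a log2 change of -1.11 ± 0.12 (SE, n = 3 per group, adjusted p = 1.73e-05). A second Stat3 probe set was also lower, at -0.92 ± 0.13, and another pair stood at 0.80 ± 0.27 and 0.12 ± 0.20. Stat3 signal still rose in the STAT3-deficient cells, by 1.00 ± 0.12 with IL-6 and by 1.77 ± 0.12 with IL-27. Which part of the transcript each probe set reads relative to the deleted part is not given in the sources used here, so these values may not measure the intact transcript. With the mean of all 4 Stat3 probe sets the difference between genotypes was -0.28 (adjusted p = 0.0803, and from 2.34e-06 to 0.0803 over all alternatives).

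The first comparison asked what IL-6 did to WT cells. IL-6 raised Gbp2, an interferon-inducible GTPase, by 4.53 ± 0.18 (23.1-fold), and Socs3, the feedback inhibitor of IL-6 receptor signalling, by 4.18 ± 0.15 (18.2-fold). It also raised Gadd45g, a stress and growth arrest gene, by 3.91 ± 0.41, Elovl6, a fatty acid elongase, by 3.85 ± 0.13, and Gzma, a cytotoxic granule protease, by 3.33 ± 0.33. Plscr1, Gbp3 and Myo6 rose by 3.16 ± 0.34, 3.14 ± 0.22 and 3.10 ± 0.29. The largest decreases were in Pdlim4 at -2.67 ± 0.30, Kcnip2 at -2.32 ± 0.62, and Epas1, a hypoxia-inducible transcription factor, at -1.88 ± 0.20. Adgre5 and the integrin chain Itga4 each fell by 1.83, with SE 0.09 and 0.12, and Cd5, a negative regulator of T cell receptor signalling, fell by 1.64 ± 0.11. In each gene named here as among the most changed, in this and the other comparisons of groups, all 3 arrays of one group lay beyond all 3 of the other, which chance gives for 10% of genes.

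In all, 439 genes were higher and 557 lower with IL-6 in WT cells, of which 168 and 103 changed at least 2-fold. Among the reported STAT3 targets, 18 of 31 measured genes were higher and 1 was lower (adjusted p = 8.33e-20 by the set test, adjusted p = 0.00287 with an estimated correlation, and 20 higher and 2 lower when adjusted over the list alone). They included Socs3, the survival regulator Bcl3 at 2.84 ± 0.15, the kinase Pim2 at 2.05 ± 0.12, Stat3 itself at 1.88 ± 0.12 and Batf, a transcription factor of T helper differentiation, at 1.72 ± 0.14. All 10 interferon-inducible GTPases rose, with a median change of 1.80 (adjusted p = 1.76e-27, and adjusted p = 0.00236 with an estimated correlation). Of 43 antiviral interferon-stimulated genes 25 were higher and 1 was lower (33 and 1 adjusted over the list alone), with Rtp4 at 2.87 ± 0.23, the nucleic acid sensor Zbp1 at 2.62 ± 0.21 and Oas2 at 2.54 ± 0.21. Socs1, another feedback inhibitor, rose by 1.96 ± 0.20, while Cd274, which encodes the inhibitory ligand PD-L1, rose by 0.60 ± 0.17 (1.52-fold, adjusted p = 0.0367), a call that some alternatives lost (adjusted p up to 0.163).

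Genes of the naive state mostly fell with IL-6. Of 16 naive and homing genes 11 were lower and 3 higher (adjusted p = 1.16e-04), with Dapl1 at -1.27 ± 0.12, the integrin chain Itga6 at -0.95 ± 0.08 and Cd27 at -0.86 ± 0.10, against Igfbp4, which rose by 2.91 ± 0.11. Of 14 follicular helper genes 5 were higher and 1 lower, with Bcl6, the lineage-defining repressor, at 1.79 ± 0.16, the costimulator Icos at 1.09 ± 0.14 and the cytokine Il21 at 1.09 ± 0.29. Of 12 genes of the Th17 program 4 were higher, among them Batf and the aryl hydrocarbon receptor gene Ahr at 1.08 ± 0.26. The follicular helper and Th17 sets passed the set test (each with adjusted p = 0.00343), but had adjusted p = 0.124 and adjusted p = 0.061 with an estimated correlation. Of 18 genes of MHC class I and antigen processing 7 were higher, led by their transactivator Nlrc5 at 1.15 ± 0.12 (adjusted p = 9.25e-05, and adjusted p = 0.124 with an estimated correlation). Among 14 Th1 program genes 3 were higher and 1 lower (adjusted p = 0.0179), with Il12rb2, a chain of the IL-12 receptor, at 1.47 ± 0.36. Tbx21, the Th1 transcription factor, stood at 0.56 ± 0.27 and did not pass (adjusted p = 0.289). Apoptosis regulators were higher in 5 and lower in 2 of 21 (adjusted p = 0.00343), with the death receptor Fas at 1.74 ± 0.27 and the survival factor Mcl1 at 0.97 ± 0.13. Some alternatives lost the calls of Kcnip2, Il21, Il12rb2 and Ahr, with adjusted p up to 0.105, 0.168, 0.0808 and 0.0834.

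The JAK-STAT list had 9 higher and 3 lower of 29 genes with IL-6 in WT cells (adjusted p = 9.97e-04). Its median of 0.03 was close to 0, and was -0.0039 with the deposited scaling, while its mean was 0.45, so its call rested on a few strong genes such as Socs3, Pim2 and Socs1. No other list passed the set test in this comparison (adjusted p from 0.181 to 0.993). Their members included the cell cycle gene Mcm4, which rose 2.38-fold as the only called gene of 20, and Cd28, the main costimulatory receptor, at -1.07 ± 0.11 among 2 higher and 4 lower of 22 co-inhibitory and co-stimulatory molecules. Of 25 chemokine and cytokine receptors 4 were higher and 5 lower, with Cxcr4 at -1.44 ± 0.22. Glycolysis genes were 1 higher and 3 lower of 17, heat shock and stress genes 1 higher and 1 lower of 21, T cell activation and immediate early genes 4 higher and 3 lower of 29, and regulatory T cell and IL-10 genes 2 higher and 2 lower of 15. Th2 program genes were 1 higher and 2 lower of 6, with Gata3, the Th2 transcription factor, at -1.02 ± 0.19. Of the lists of other cell types, B cell markers had 1 lower of 14, and CD8 T and NK cell markers 1 higher and 1 lower of 6, namely Gzma and Klrd1 at -1.54 ± 0.16. None of the 11 myeloid markers, 3 red blood cell markers and 22 ribosomal protein genes was called by limma (1, 0 and 0 at an unadjusted p under 0.05). The red blood cell list was too short for the set test.

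**Figure D1:**
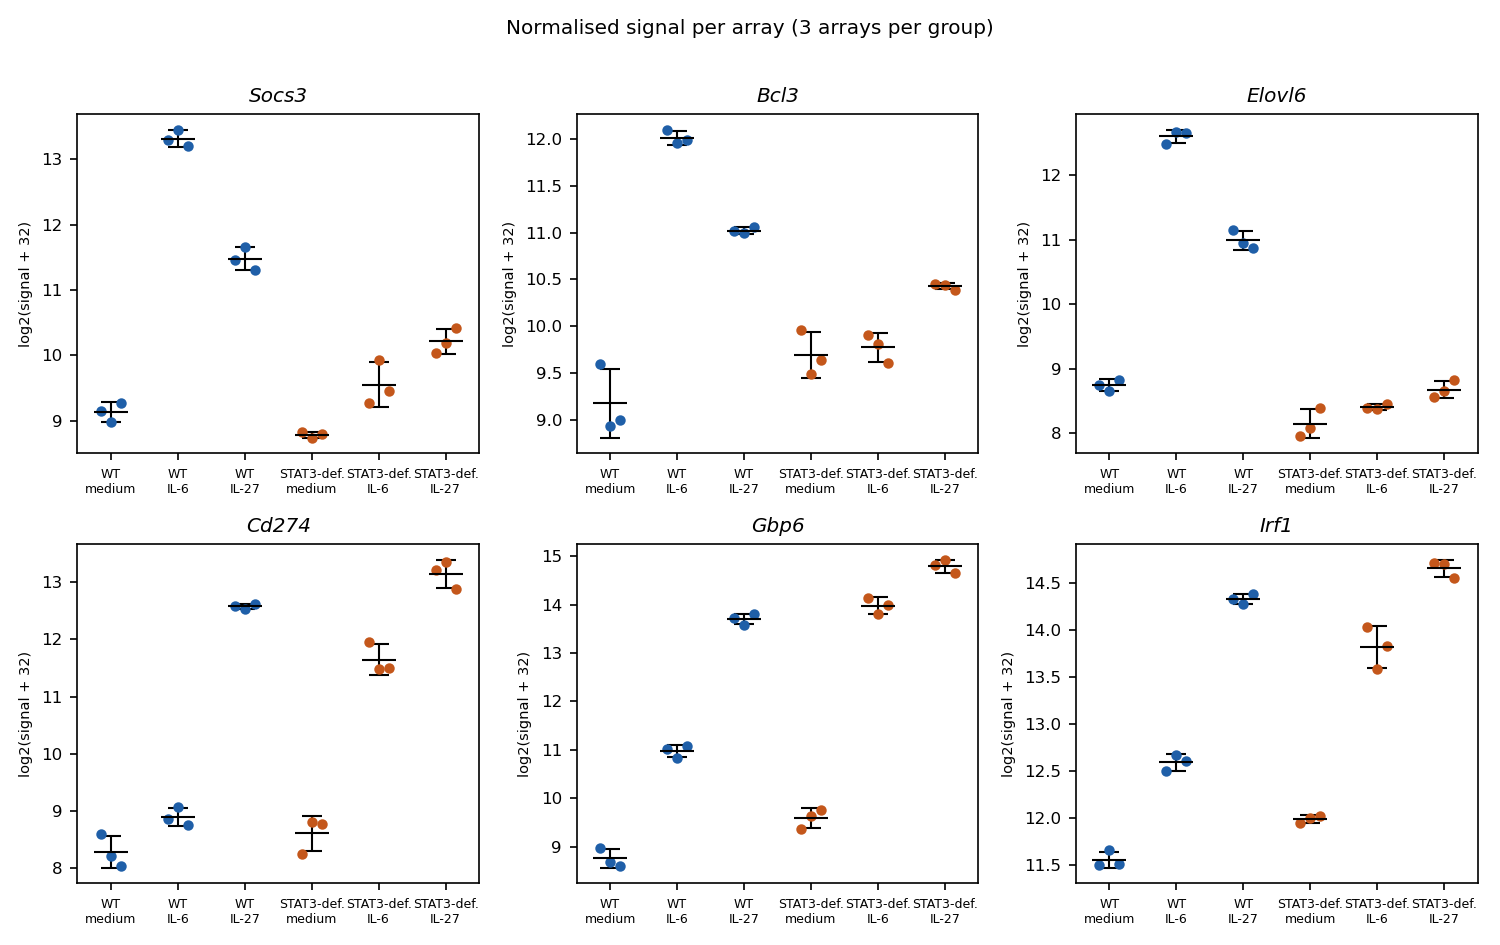
Normalised signal on the log2 scale for 6 genes, with the points for single arrays, the mean as a line and the SD as bars (3 arrays per group). Socs3, Bcl3 and Elovl6 rose with IL-6 in WT cells by 4.18, 2.84 and 3.85 and by at most 0.77 in STAT3-deficient cells, while Cd274 and Gbp6 rose more with IL-6 without STAT3.

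The next comparison asked what IL-27 did to WT cells. The interferon-inducible GTPases led it, with Iigp1 at 5.62 ± 0.15 (49.1-fold), Gbp2 at 5.29 ± 0.18, Gbp6 at 4.95 ± 0.12 and Irgm1 at 4.58 ± 0.17. Cd274 rose by 4.28 ± 0.17 (19.5-fold, adjusted p = 2.39e-12), and Oasl2, an antiviral gene, by 4.54 ± 0.97. Among regulators of T cell responses, Socs1 rose by 3.28 ± 0.20, the interferon response factor Irf1 by 2.77 ± 0.09, Socs3 by 2.34 ± 0.15 and Tbx21 by 2.03 ± 0.27. The decreases were smaller, with Pdlim4 at -1.98 ± 0.30, Itpripl2 at -1.78 ± 0.48, the chemokine Ccl5 at -1.50 ± 0.27 and Epas1 at -1.47 ± 0.20. Il27ra, a chain of the IL-27 receptor, was lower by -0.59 ± 0.14. The calls of Itpripl2, Ccl5 and Il27ra were lost in some alternatives, with adjusted p up to 0.143, 0.076 and 0.107.

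In this comparison 324 genes were higher and 240 lower, of which 162 and 24 changed at least 2-fold. All 10 interferon-inducible GTPases rose, with a median of 4.09 (adjusted p = 6.05e-56), as did 38 of 43 antiviral genes (40 adjusted over the list alone), with a median of 1.62 (adjusted p = 1.16e-70). With an estimated correlation these lists had adjusted p = 6.97e-05 and adjusted p = 1.31e-04. MHC class I and antigen processing genes were higher in 12 of 18 (adjusted p = 2.13e-21), with Nlrc5 at 2.38 ± 0.12 and the immunoproteasome subunits Psmb9 and Psmb10 at 1.88 ± 0.16 and 1.51 ± 0.11. Of the 31 reported STAT3 targets 9 were higher (adjusted p = 1.55e-08), including Bcl3 at 1.85 ± 0.15 and Bcl6 at 1.41 ± 0.16. Of 16 naive and homing genes 9 were lower and 1 higher (adjusted p = 1.24e-06), with Dapl1 at -1.05 ± 0.12 and Klf2, which controls lymph node homing, at -0.50 ± 0.07. Apoptosis regulators were higher in 6 of 21 (adjusted p = 7.09e-04). The JAK-STAT list was higher in 7 and lower in 2 of 29 (adjusted p = 0.0143, and adjusted p = 0.109 with an estimated correlation), with a median of 0.01 and a mean of 0.37. The Th17 and follicular helper lists, with 2 higher of 12 and 1 higher and 1 lower of 14, did not pass (adjusted p = 0.445 and adjusted p = 0.908). Nor did the Th1 list, with 3 higher and 1 lower of 14 (adjusted p = 0.131 by the set test).

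Both cytokines shared medium controls, and 192 genes were higher and 194 lower with both in WT cells, where 11.9 and 11.2 were expected from independent calls, and 1 gene went opposite ways. That expectation leaves out the shared controls, so part of the excess may come from them. Across genes, which are not independent replicates, the changes correlated with r = 0.67, against 0.50 for simulated changes that shared only the controls, with a covariance of 0.104 against 0.0313.

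Set directly against IL-6 in WT cells, IL-27 gave higher Cd274, by 3.68 ± 0.17 (12.8-fold, adjusted p = 7.51e-11). Irgm1, Iigp1 and Gbp8 were higher by 3.21 ± 0.17, 3.17 ± 0.15 and 2.88 ± 0.10, the chemokine Cxcl10 by 2.60 ± 0.42, the transcription factor Irf8 by 2.16 ± 0.18 and Tbx21 by 1.47 ± 0.27. IL-27 gave lower Gadd45g at -2.79 ± 0.41, the protease inhibitor Serpinb1a at -2.72 ± 0.42, the kinase Map3k8 at -2.70 ± 0.24, Gzma at -2.55 ± 0.33, Igfbp4 at -2.38 ± 0.11 and Socs3 at -1.84 ± 0.15. Without the filter on dim probe sets Serpinb1a had -0.78 and was not called (adjusted p = 0.331, the highest over its alternatives, and 1.16e-07 the lowest). Il6st was lower with IL-27 than with IL-6 by -1.10 ± 0.12. In all, 212 genes were higher and 164 lower with IL-27, a total of 376 that was 588 with blocks by sample number within genotype. Every one of the 10 GTPases was higher (adjusted p = 5.78e-42), as were 18 of 43 antiviral genes (27 adjusted over the list alone, adjusted p = 9.71e-30) and 10 of 18 MHC class I genes (adjusted p = 6.45e-17). Reported STAT3 targets were lower in 12 of 31 (14 adjusted over the list alone, adjusted p = 1.43e-12), including Bcl3 at -0.99 ± 0.15, Batf at -0.85 ± 0.14 and Hif1a at -1.12 ± 0.16. The follicular helper and Th17 lists were each lower in 3 genes, of 14 and 12 (adjusted p = 1.04e-04 and adjusted p = 0.00169), and both had adjusted p = 0.0623 with an estimated correlation.

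In STAT3-deficient cells, IL-6 raised the same class of genes that led the IL-27 response. Gbp6 rose by 4.39 ± 0.12, Gbp2 by 4.23 ± 0.18, Iigp1 by 4.08 ± 0.15, Zbp1 by 3.94 ± 0.21 and Rtp4 by 3.93 ± 0.23. Cd274 rose by 3.03 ± 0.17 (8.17-fold, adjusted p = 6.87e-10), the interferon regulator Irf7 by 2.50 ± 0.15 and Tbx21 by 1.60 ± 0.27. Socs3 rose by 0.77 ± 0.15, and the values of Bcl3, Bcl6 and Batf were 0.08 ± 0.15, 0.15 ± 0.16 and -0.09 ± 0.14, none of which passed. The few decreases included Wasf1, an actin regulator, at -1.24 ± 0.27, St6galnac3 at -1.06 ± 0.22 and Dapl1 at -0.62 ± 0.12. In some alternatives these 3 decreases and the rise of Socs3 were not called, with adjusted p up to 0.11, 0.209, 0.0925 and 0.16.

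Here 202 genes were higher and 19 lower, of which 104 and 2 changed at least 2-fold, while 190 and 11 passed with the deposited scaling and 219 and 3 with median centring, so the number of decreases depended on the scaling. All 10 GTPases rose, with a median of 3.02 (adjusted p = 2.26e-69), as did 39 of 43 antiviral genes (43 adjusted over the list alone), with a median of 1.96 (adjusted p = 5.05e-127), and 12 of 18 MHC class I genes (adjusted p = 3.84e-27). With an estimated correlation these lists had adjusted p = 1.1e-05, 1.1e-05 and 0.00105. Of the 202 genes, 171 were also higher with IL-27 in WT cells, where 5.5 were expected from independent calls, and 112 were also higher with IL-6 in WT cells. The reported STAT3 targets were higher in 3 of 31, namely Pim2 at 1.69 ± 0.12, Stat3 and Socs3 (adjusted p = 4.49e-05, and adjusted p = 0.0983 with an estimated correlation). The naive list fell in 1 of 16, with a median of -0.13 (adjusted p = 0.00552) that became 0.03 with median centring. The Th1 list was higher in 1 of 14, Tbx21 (adjusted p = 3.97e-04), and apoptosis regulators in 2 of 21 (adjusted p = 5.97e-05), the transcriptional corepressor Daxx at 1.15 ± 0.10 and Casp8 at 0.57 ± 0.08. The JAK-STAT list was higher in 5 of 29 (adjusted p = 0.0449, and adjusted p = 0.163 with an estimated correlation), with a mean of 0.20 and a median of -0.03 that turned to 0.03 with the deposited scaling and 0.12 with median centring. With only the 6 arrays of these groups in the model, 127 genes passed, of which 126 were higher.

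IL-27 in STAT3-deficient cells again led with Gbp6 at 5.20 ± 0.12 (36.9-fold), Gbp2 at 5.06 ± 0.18, Iigp1 at 4.97 ± 0.15 and Cd274 at 4.53 ± 0.17 (23.1-fold, adjusted p = 9.83e-13). Socs1 rose by 3.74 ± 0.20, Tbx21 by 2.92 ± 0.27, Irf8 by 2.79 ± 0.18, Irf1 by 2.67 ± 0.09 and Il12rb2 by 2.46 ± 0.36. Bcl6 and Socs3 rose by 1.06 ± 0.16 and 1.43 ± 0.15. The lowest were Pik3r2, a regulatory subunit of phosphoinositide 3-kinase, at -1.44 ± 0.39, the hormone gene Sct at -1.36 ± 0.37, Sebox at -1.26 ± 0.30 and Pdlim4 at -1.22 ± 0.30. Each of these 4 decreases lost its call in some alternatives (adjusted p up to 0.171, 0.14, 0.124 and 0.12). Here 392 genes were higher and 204 lower, so that 65.8% of the calls were increases, against 91.5% with median centring. With only the 6 arrays of these groups in the model 349 genes passed.

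All 10 GTPases rose with IL-27 without STAT3, with a median of 4.06 (adjusted p = 6.04e-52), as did 41 of 43 antiviral genes (42 adjusted over the list alone), with a median of 2.04 (adjusted p = 4.10e-86), and 13 of 18 MHC class I genes (adjusted p = 5.52e-23). The Th1 list was higher in 5 of 14 (adjusted p = 0.0016), including Tbx21, Il12rb2, the IL-18 receptor chain Il18r1 at 0.97 ± 0.24 and Runx3 at 0.92 ± 0.21. Apoptosis regulators were higher in 4 of 21 (adjusted p = 3.26e-04). Reported STAT3 targets were higher in 7 of 31 (adjusted p = 5.75e-07), with Pim2 at 2.43 ± 0.12 and the transcription factor Irf4 at 2.14 ± 0.45, and naive and homing genes lower in 7 of 16 (11 adjusted over the list alone, adjusted p = 1.78e-08). Il18r1, Runx3 and Irf4 were not called in some alternatives, with adjusted p up to 0.12, 0.078 and 0.0633. The JAK-STAT list was higher in 6 of 29 (adjusted p = 0.036, and adjusted p = 0.163 with an estimated correlation), with a mean of 0.36 and a median of -0.02 that turned to 0.04 with the deposited scaling and 0.16 with median centring.

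**Figure D2:**
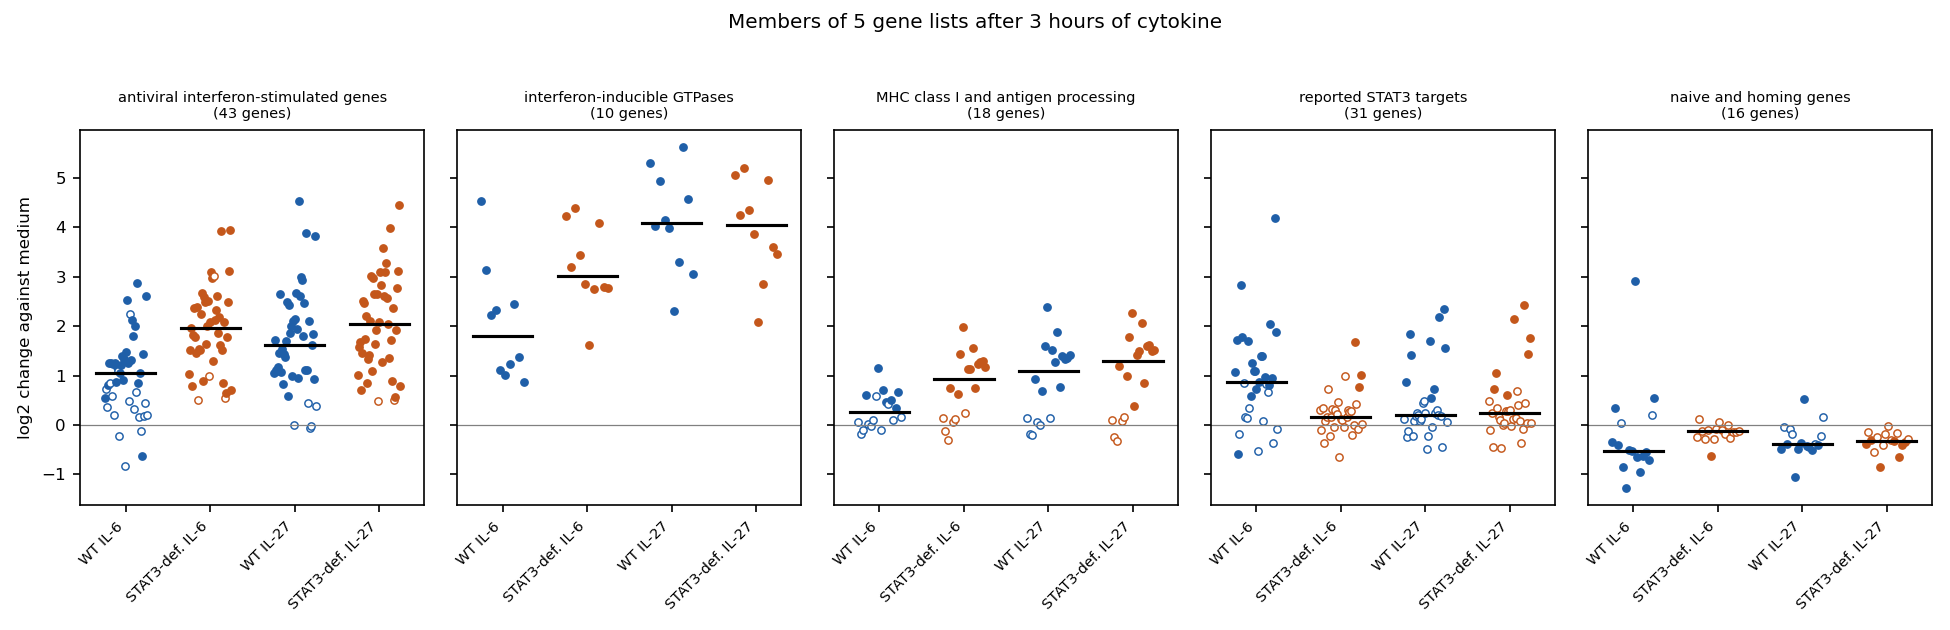
Log2 change against medium of each measured member of 5 gene lists, with filled points for genes with an adjusted p under 0.05 and a bar at the list's median. The median of the interferon-inducible GTPases was 1.80 with IL-6 in WT cells, 3.02 with IL-6 in STAT3-deficient cells, and 4.09 and 4.06 with IL-27 in WT and STAT3-deficient cells.

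Set against IL-6 in STAT3-deficient cells, IL-27 gave higher Cxcl10 by 2.02 ± 0.42, Irf8 by 1.93 ± 0.18, Gsap by 1.88 ± 0.39, Socs1 by 1.84 ± 0.20, Cd274 (2.83-fold) and Tbx21 by 1.32 ± 0.27. Adgre5 was the only lower gene, at -0.55 ± 0.09, and 46 genes were higher. Calls were lost in some alternatives for Cxcl10, Gsap, Tbx21, Adgre5 and Parp14, with adjusted p up to 0.207, 0.271, 0.407, 0.19 and 0.141. Of the 10 GTPases 8 were higher, with a median of 0.82 (adjusted p = 8.26e-26), and the naive list was lower by a median of -0.18 (adjusted p = 3.83e-08) with no gene called by limma (6 at an unadjusted p under 0.05). This median was -0.13 with the deposited scaling and -0.10 with median centring, and lay between -0.16 and -0.20 with an array left out. The arrays of these 2 groups also parted across the cytokines, with IL-6 array 1 and IL-27 arrays 1 and 2 at 19.1 to 25.2 on the third principal component and the other 3 at -13.5 to -6.33, so small shifts such as that of the naive list are less secure here. The antiviral list was higher in 3 of 43 (adjusted p = 0.0169), with Parp14 at 0.75 ± 0.13, and the STAT3 target list in 3 of 31 (adjusted p = 6.02e-04), but had adjusted p = 0.467 and adjusted p = 0.247 with an estimated correlation. The MHC class I list passed the set test with no gene called by limma (8 at an unadjusted p under 0.05, adjusted p = 9.03e-07), and had adjusted p = 0.16 with an estimated correlation. The JAK-STAT list was higher in 3 of 29 (adjusted p = 0.0228, and adjusted p = 0.222 with an estimated correlation), with a mean of 0.15 against a median of -0.01 that was 0.02 with median centring. The count of 47 genes fell to 24 without IL-6 array 2, 29 without IL-6 array 3, 26 without IL-27 array 1 and 31 without IL-27 array 2, and it was 17 with only the 6 arrays of these groups in the model, 28 without the trend of variance on mean, and 74 with the blocks by sample number.

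The IL-6 effect was then compared between genotypes with an interaction term. It was smaller in STAT3-deficient cells for Elovl6 by -3.59 ± 0.18, Socs3 by -3.41 ± 0.21 (adjusted p = 1.36e-08), Gadd45g by -3.03 ± 0.59, Slco4a1 by -2.94 ± 0.64, Serpinb1a by -2.91 ± 0.59, Rragd, a GTPase of nutrient sensing, by -2.86 ± 0.37, Igfbp4 by -2.85 ± 0.15 and Bcl3 by -2.76 ± 0.21. It was larger for Cd274 by 2.43 ± 0.25 (adjusted p = 7.67e-06), Usp18, an interferon-induced protease that damps interferon signalling, by 2.30 ± 0.38, Gbp6 by 2.17 ± 0.17 and Irgm2 by 1.89 ± 0.23. Positive values also came from genes that fell with IL-6 in WT cells, namely Pdlim4 at 2.20 ± 0.42, Slco3a1 at 2.02 ± 0.37 and Sntb1 at 1.87 ± 0.25. Xaf1, an interferon-stimulated gene of apoptosis control, had 2.66 ± 0.21 on its main probe set and -0.21 ± 0.25 on its other one. Batf, Il21 and Bcl6 had smaller effects without STAT3, by -1.81 ± 0.20, -1.74 ± 0.41 and -1.64 ± 0.23, and Gata3 a higher one by 1.39 ± 0.27. Serpinb1a had -0.75 without the filter on dim probe sets (adjusted p = 0.633, the highest over its alternatives, and 6.5e-06 the lowest), and some alternatives lost the calls of Slco4a1 and Il21 (adjusted p up to 0.0651 and 0.0759).

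The difference was positive for 219 genes and negative for 150, and for 394 and 241 with blocks by sample number within genotype, whose meaning the labels do not give. Of the 439 genes raised by IL-6 in WT cells the effect differed in 173 and was smaller without STAT3 in 146 of these, and the median change of the 439 was 0.85 in WT and 0.17 in STAT3-deficient cells. Of the 557 genes lowered by IL-6 in WT cells the difference was positive, against the decrease, in 162, and their median was -0.69 in WT and -0.13 in STAT3-deficient cells. These medians come from genes chosen by their call in WT cells, which favours larger values there. Reported STAT3 targets had a smaller IL-6 effect without STAT3 in 12 of 31 and a positive difference in 1, Bcl2, which had -0.59 in WT and 0.34 in STAT3-deficient cells (15 and 2 adjusted over the list alone, adjusted p = 5.35e-13). The list holds Stat3, the deleted gene itself. Its difference of -0.87 ± 0.17 on its main probe set may not measure the intact transcript and does not count as a target's response. The GTPases had a larger effect in 8 of 10, with a median difference of 1.47 (adjusted p = 1.73e-15), and the antiviral genes a more positive one in 16 of 43 (30 adjusted over the list alone), with a median of 0.82 (adjusted p = 3.86e-26). The signs of both medians were the same under all 3 scalings. Of the 202 genes raised by IL-6 without STAT3 the effect was larger than in WT cells in 58. Genotype coincided with a difference in the hybridization controls, given below. A processing difference that altered the response to IL-6 or IL-27 therefore cannot be told apart from genotype in either interaction.

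MHC class I genes had a larger IL-6 effect without STAT3 in 6 of 18, with Psmb9 at 1.13 ± 0.22 and the peptide transporter Tap1 at 1.12 ± 0.27, whose call some alternatives lost with adjusted p up to 0.075 (list adjusted p = 6.45e-08, and adjusted p = 0.0812 with an estimated correlation). The naive list was higher in 5 and lower in 1 of 16 (adjusted p = 0.0353, and adjusted p = 0.0812 with an estimated correlation). The follicular helper list was lower in 2 of 14 and the Th17 list in 3 of 12 (adjusted p = 0.0353 and adjusted p = 0.0227), and had adjusted p = 0.3 and adjusted p = 0.155 with an estimated correlation. The JAK-STAT list was higher in 2 and lower in 5 of 29 (adjusted p = 0.0411, and adjusted p = 0.2 with an estimated correlation).

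The IL-27 effect differed between genotypes in only 2 of the 11971 genes, Xaf1 at 2.18 ± 0.21 (adjusted p = 3.83e-05) and Elovl6 at -1.72 ± 0.18 (adjusted p = 9.08e-05), while 878 genes had an unadjusted p under 0.05. The second Elovl6 probe set had -1.47 ± 0.27, and the second Xaf1 probe set had -1.47 ± 0.25, against the sign of the first. With the mean of its probe sets Xaf1 had 0.35 (adjusted p = 0.728, and from 9.59e-08 to 0.728 over all alternatives). Cd274 differed by 0.25 ± 0.25, Socs3 by -0.91 ± 0.21 (adjusted p = 0.372), Bcl3 by -1.11 ± 0.21 (adjusted p = 0.141) and Batf by -0.97 ± 0.20 (adjusted p = 0.154). These 3 were called in some alternatives, Socs3 and Batf with array weights (adjusted p = 0.0438 for each) and Bcl3 without WT medium array 1 (adjusted p = 0.00308), with adjusted p up to 0.734, 0.512 and 0.465 in others. Over the 564 genes called with IL-27 in WT cells, 95.2% had the same sign without STAT3, and the slope of the STAT3-deficient on the WT change was 0.91 (95% interval 0.877 to 0.943). Of these genes, 245 of the 324 higher and 99 of the 240 lower were called the same way in STAT3-deficient cells. The count of shared decreases depends on the scaling. In all, 204 genes were lower with IL-27 in STAT3-deficient cells here, 123 with the deposited scaling and 44 with median centring. For the 996 genes called with IL-6 in WT cells the slope was 0.333 (95% interval 0.30 to 0.366). Both intervals are taken over genes, which are not independent replicates. The antiviral list had a median difference of 0.42 (adjusted p = 5.80e-06), which had adjusted p = 0.356 with an estimated correlation. An interaction has a median SE of 0.261, and simulated 2-fold differences were recovered in 45.4% of cases and 4-fold ones in 84.2%, so smaller differences could go undetected. The count was 4 without IL-27 array 3 of the STAT3-deficient cells, 1 higher and 2 lower with either other scaling, and 13 with array weights. The median of all genes was 0.03, and 0.11 with median centring.

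**Figure D3:**
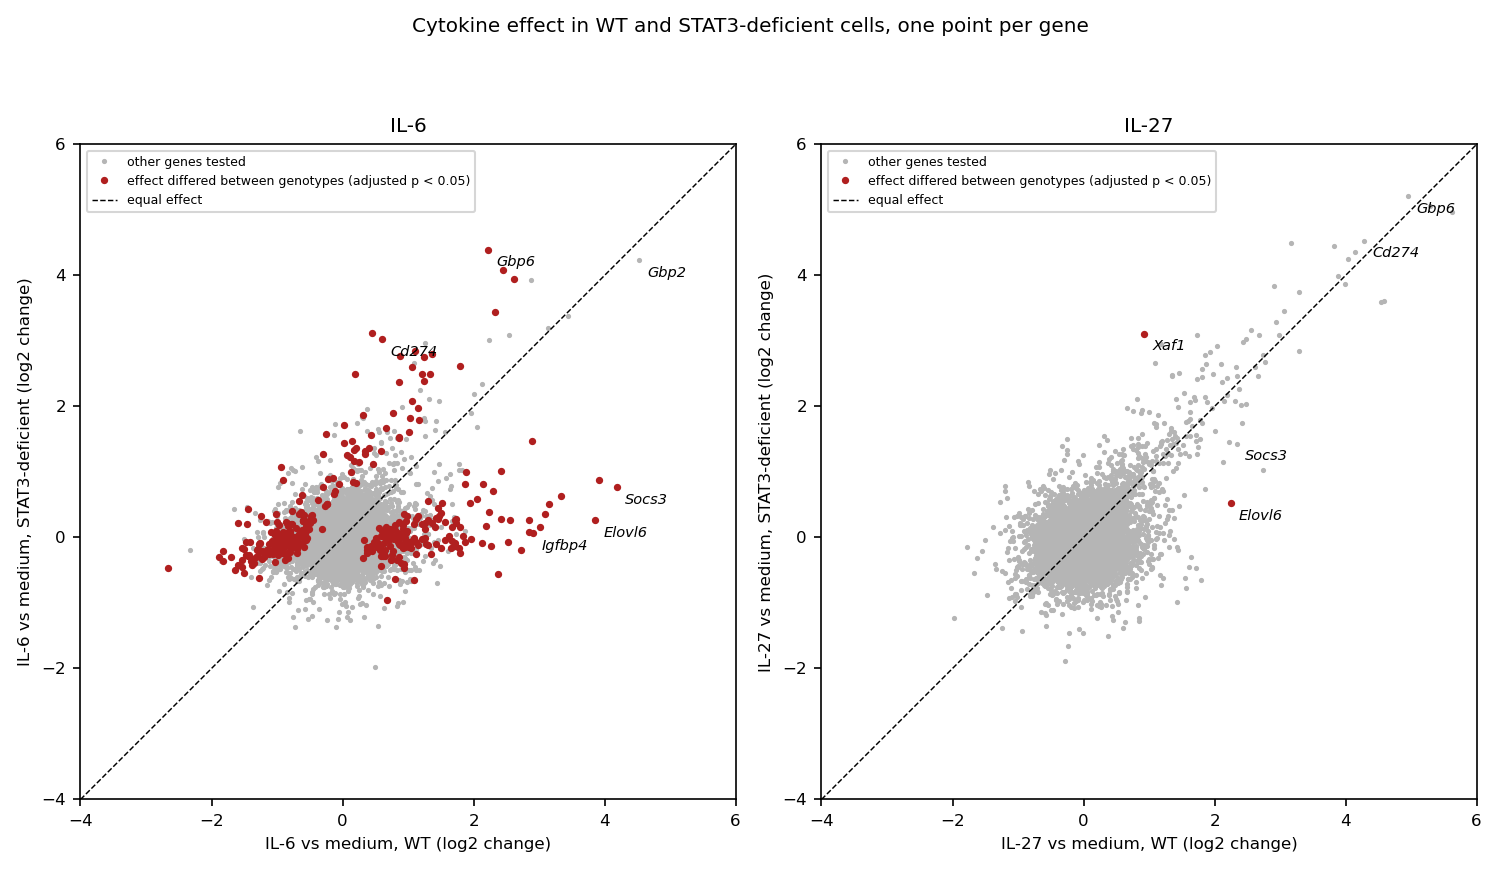
Log2 change with each cytokine in STAT3-deficient cells (vertical axis) against WT cells (horizontal axis), one point per gene. For IL-6 the effect differed between genotypes in 369 genes, drawn in red, and for IL-27 in 2, Xaf1 and Elovl6.

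The last comparison set STAT3-deficient against WT cells in medium. Hybridization controls were brighter on all WT arrays, so the genotype here cannot be told apart from a difference in how the arrays were processed. Many of the genes that were highest in STAT3-deficient cells are known from other cell types. They included S100a8 and S100a9, calcium-binding proteins of neutrophils and monocytes, at 5.39 ± 0.38 (41.9-fold) and 5.08 ± 0.56, the immunoglobulin genes Igkv8-30 and Igha at 4.64 ± 0.39 and 4.62 ± 0.68, and the MHC class II genes H2-Ab1 and H2-Aa at 3.48 ± 0.39 and 3.14 ± 0.48. Xaf1 was higher by 3.31 ± 0.15 on its main probe set and lower by -1.98 ± 0.18 on its other one. Cpm, a carboxypeptidase, was lower at -2.60 ± 0.20, Sytl1 at -2.15 ± 0.60 and Pafah2 at -2.09 ± 0.42. Of 14 B cell markers 10 were higher (11 adjusted over the list alone), and of 11 myeloid markers 7 were higher and 2 lower, while none of 3 red blood cell markers was called by limma (0 at an unadjusted p under 0.05). The B cell and myeloid sets passed the set test (adjusted p = 6.87e-06 and adjusted p = 0.0438) and had adjusted p = 0.399 and adjusted p = 0.613 with an estimated correlation. In WT medium, 6 of the 14 B cell and 4 of the 11 myeloid markers also lay above the median of the array, and none of them is in another list.

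Several of these marker signals, such as S100a8, S100a9, Cd74 and H2-Aa, stood apart by genotype on every array. S100a8 was between 1196 and 3495 units on the 9 STAT3-deficient arrays and at most 106.7 on the 9 WT arrays. The T cell gene Cd3e was also higher on the STAT3-deficient arrays, at 6884 to 10350 against 2657 to 4080. Cd4 overlapped in medium, at 2380 to 3015 against 1853 to 2755. It did not overlap with IL-6, at 2076 to 3369 against 1020 to 1453, or with IL-27, at 2166 to 2988 against 1456 to 1618. A sort for CD4 T cells is meant to leave out B cells and neutrophils, but its purity is not given in the sources used here. The STAT3-deficient arrays numbered 3 had less S100a8, at 1196 to 1232, and more of the red cell gene Slc4a1, at 318.9 to 341.0, than the other STAT3-deficient arrays. With cytokine, no myeloid marker was called in either genotype by limma (the largest count at an unadjusted p under 0.05 was 3, in WT cells with IL-27). The B cell markers were not free of calls. Ighm was lower with IL-6 in WT cells, and 1 of 14 was higher with IL-6 in STAT3-deficient cells when adjusted over the list alone.

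In total 1647 genes were higher and 1543 lower in STAT3-deficient cells in medium, of which 369 and 120 differed at least 2-fold. The balance depended on the scaling, with 51.6% of calls higher here, 60.4% with the deposited scaling and 33.8% with median centring. The median of all genes was 0.03 here, 0.14 with the deposited scaling and -0.09 with median centring. Antiviral genes were higher in 11 and lower in 2 of 43 (adjusted p = 0.0438, and adjusted p = 0.891 with an estimated correlation), with Rnf213 at 1.73 ± 0.15 and Ifit3 at 1.31 ± 0.23. The GTPases were higher in 6 of 10, with Irgm1 at 1.26 ± 0.17 (adjusted p = 0.0021, and adjusted p = 0.601 with an estimated correlation). Il6ra, the IL-6 receptor chain, was lower by -0.69 ± 0.17, and Il27ra was higher by 0.43 ± 0.14. The count of 3190 fell to 2036 without WT array 1, 2064 without WT array 2 and 2067 without STAT3-deficient array 1, all in medium, and was 656 with the B cell and myeloid marker signal as a covariate, an alternative chosen after seeing the data, under which Igha and H2-Aa stood at -0.45 ± 0.91 and -0.22 ± 0.70. The covariate followed genotype closely (r = 0.961) and raised the median SE from 0.185 to 0.419, so the calls it ended do not show that marker signal explains those genes. H2-Ab1 and S100a9, which like H2-Aa are part of the covariate, shrank to 0.97 ± 0.64 and 0.77 ± 0.69, and Igkv8-30 to 2.45 ± 0.72, Irgm1 to 0.63 ± 0.38, Il27ra to 0.17 ± 0.32 and Pafah2 to -1.11 ± 0.97, each with a wider SE (adjusted p = 0.373, 0.524, 0.0552, 0.323, 0.789 and 0.514). Ifit3 at 1.17 ± 0.54 and Il6ra at -0.56 ± 0.40 nearly kept their size and Sytl1 grew to -4.28 ± 1.32, and their calls ended with the wider SE (adjusted p = 0.198, 0.417 and 0.0635). Il27ra was not called with either other scaling, and stood at 0.11 with median centring.

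**Figure D4:**
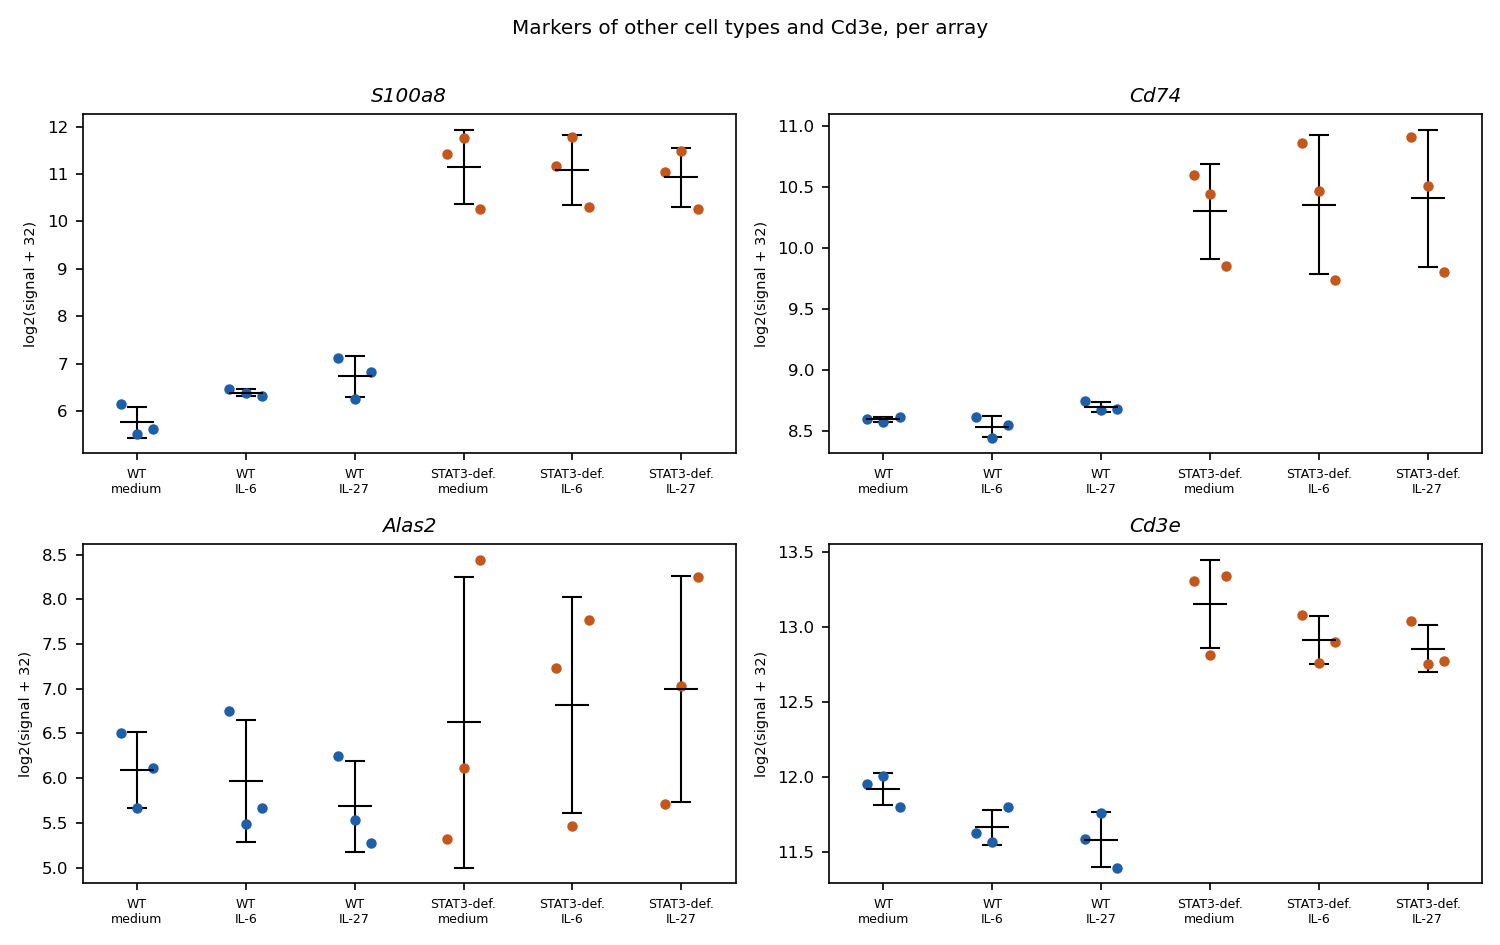
Normalised signal on the log2 scale of S100a8 (neutrophils and monocytes), Cd74 (antigen-presenting cells), Alas2 (red cells) and Cd3e (T cells), with the points for single arrays, the mean as a line and the SD as bars (3 arrays per group). All 9 STAT3-deficient arrays lie above all 9 WT arrays for S100a8, Cd74 and Cd3e.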

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

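The tests of Stat3 neighbours and of other splits were planned, and the tests of compressed changes, other cells, array run and the second Xaf1 probe set were chosen after the results were seen.

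The IL-6 effect differed between genotypes in 369 genes by the interaction term. The 8 largest positive differences among called genes were in Xaf1 at 2.66, Cd274 at 2.43, Usp18 at 2.30, Pdlim4 at 2.20, Gbp6 at 2.17, Slco3a1 at 2.02, Irgm2 at 1.89 and Sntb1 at 1.87. The 8 largest negative ones were in Elovl6 at -3.59, Socs3 at -3.41, Gadd45g at -3.03, Slco4a1 at -2.94, Serpinb1a at -2.91, Rragd at -2.86, Igfbp4 at -2.85 and Bcl3 at -2.76. For raised genes, the data argue against a general compression of changes on the STAT3-deficient arrays. The IL-27 changes there followed those in WT cells with a slope of 0.91 (95% interval 0.877 to 0.943). This interval is taken over genes, which are not independent replicates. Genes raised by IL-27 in WT cells had a median of 1.00 in WT and 0.97 in STAT3-deficient cells. Those lowered had -0.59 and -0.38, so a compression of decreases is not excluded. A dilution by other cells that shrank all IL-6 effects alike would not enlarge those of the interferon-inducible GTPases, which differed by a median of 1.47 in the other direction. That median was known when this test was chosen. Dilution that differs between genes was not tested and stays open for the smaller effects. Of 100 splits of the arrays, from 200 possible, 5 gave as many genes, and the highest other gave 633, but all 4 others kept the WT groups whole and so still held the IL-6 effect of WT cells, which makes this count no clean test of chance. The 83 splits that mixed both genotypes gave at most 0 genes by limma against 369. At an unadjusted p under 0.05 they gave up to 1732 (median 409) against 1512. Mixing puts real effects into the spread within groups, which tends to lower these counts. This breakdown, chosen after seeing the counts, does not settle chance for the total, while Socs3 alone had an adjusted p = 1.36e-08. A change in the IL-6 response through loss of STAT3 remains open as the design's own explanation. Genotype coincided with a difference in the hybridization controls, so a processing difference that altered the IL-6 response cannot be told apart from it. For genes with a larger effect without STAT3, a response of other cells in the sort remains open as well. With the marker signal as a covariate 431 genes were called, and Socs3 and Cd274 stood at -3.40 and 2.40. The covariate adjusts only the level of each array, so it cannot test whether other cells responded to IL-6.

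Cells in medium differed between genotypes in 3190 genes, and this pattern is confounded, since genotype coincides with a difference in the hybridization controls. Array runs are not given in the sources used here. All 18 hybridization controls, which are added to each array and do not come from the cells, were brighter on WT arrays. Their ratios of means ran from 4.04 to 34.4, with a lowest WT over highest STAT3-deficient array ratio of 3.39. Genotype therefore cannot be told apart from a difference in how the arrays were processed. Among the 100 tested genes nearest to Stat3 on its chromosome, 37 were called against 26.6% of all others (odds ratio 1.62, 95% interval 1.05 to 2.48, p = 0.0228 by Fisher's exact test, two-sided), which leaves open whether DNA carried along with the deleted allele adds to it. Other cells in the STAT3-deficient sort are a candidate source of the B cell and myeloid signal: the 17 markers called higher moved together around their group means over the 9 STAT3-deficient arrays, with a mean pairwise correlation of 0.55 against a 95th percentile of 0.0782 for random gene sets, and S100a8 reached 3495 units there. Of the markers listed by array, Cd74, H2-Aa, Cd79b, S100a8 and S100a9 were lowest on the arrays numbered 3, while H2-Ab1 and Lyz1 were not. The shared movement may thus largely be a contrast of those arrays with the others, so the 9 arrays may not be independent. The random sets were matched for mean signal only, so this percentile does not decide where the marker signal came from. A genotype effect on the T cells themselves stays open as well.

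The IL-27 effect differed between genotypes in 2 genes, Xaf1 at 2.18 and Elovl6 at -1.72. The second Xaf1 probe set differed by -1.47, and its level in medium was lower rather than higher in STAT3-deficient cells. A candidate explanation for Xaf1 is therefore that its main probe set reads a sequence or isoform that differs between the mice. Chance is not excluded for this count: 12 of 100 splits gave as many genes, up to 206, and 10 of the 11 others kept the arrays of a genotype in their groups, so that they still held that genotype's IL-27 effect. The 84 splits that mixed both genotypes gave up to 2 genes, as many as the real one. For Elovl6 both probe sets had the same sign and no explanation was tested.

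Groups of 3 against 3 make 10 splits, too few for a share under 0.05. In the other splits each group mixes arrays of both conditions, so a real difference widens the spread within groups and tends to hold their counts down. Low counts in these splits therefore do not show that the calls are sound. The real split was the only 1 with as many genes, and the highest other gave 0 against 996 for IL-6 in WT cells, 2 against 564 for IL-27 in WT cells, 0 against 376 for IL-27 against IL-6 in WT cells, 12 against 221 for IL-6 and 4 against 596 for IL-27 in STAT3-deficient cells, and 1 against 3190 for the genotypes in medium. For IL-27 against IL-6 in STAT3-deficient cells 2 of the 10 splits gave as many, and the other gave 1081 against 47, which points to a structure of these samples that crosses the groups. That split set IL-6 array 1 with IL-27 arrays 1 and 2, whose median signals were 131.5, 155.2 and 132.9, against arrays with 173.9, 158.4 and 174.6.

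Probe sets without a single gene symbol also responded. In the same model 183 of 5321 such probe sets were called with IL-6 and 97 with IL-27 in WT cells, and which genes they read was not analysed here. They include probe sets listed with several symbols.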

How the results depend on the processing

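The alternatives that left out the STAT3-deficient arrays numbered 3 or used marker signal as a covariate were chosen after seeing the data. Counts outside 1.5 times their value were these. With a 2-fold minimum 271, 186 and 102 genes were called in WT cells (IL-6, IL-27, IL-27 against IL-6), 106, 193 and 14 in STAT3-deficient cells, 172 for the IL-6 interaction and 489 for the genotypes in medium, by construction. With only the arrays compared the STAT3-deficient counts were 127, 349 and 17, and without a variance trend the last was 28. Array weights gave 931 for IL-27 in WT cells and 13 for the IL-27 interaction, which was 1 with the mean of probe sets and 6 without the arrays numbered 3. Blocks by sample number within genotype gave 588 and 74 for IL-27 against IL-6 in WT and STAT3-deficient cells and 635 for the IL-6 interaction, and the labels do not say what the numbers mean. Of 18 pairs with the same number and genotype 11 had a correlation of residuals above 0.1 (from -0.15 to 0.36), and 14 of 18 arrays correlated best with their own number within genotype. On STAT3-deficient arrays some marker signals followed the number. H2-Aa was 1442.4, 1421.7 and 1471.5 on arrays 1 (medium, IL-6, IL-27), 1051.9, 1090.8 and 1185.8 on arrays 2, and 461.9, 481.1 and 424.5 on arrays 3. Lyz1 did not follow it, at 160.6, 636.5 and 580.2 on arrays 1. Arrays with the same number may thus share a source, which the model without blocks leaves out, though the residuals fall short of pairing throughout. The covariate gave 656 for the genotypes in medium. Leaving out each array in turn gave 754 to 864, 393 to 469, 282 to 301, 179 to 202, 428 to 705, 24 to 47, 272 to 382, 2 to 4 and 2036 to 2927 genes, in the order of the comparisons, with fewer arrays.

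The sign of the JAK-STAT list's median changed most often, and the cause was not tested. For IL-6 in WT cells (0.03) it was -0.0039 with the deposited scaling, -0.0046 with array weights, and -0.0027 (without medium array 2) to 0.062 when an array was left out. For IL-27 in WT cells (0.01) it was -0.0071 with the covariate and -0.0796 to 0.038 with an array left out, negative without medium array 1 or 2 or IL-27 array 3. For IL-6 in STAT3-deficient cells (-0.03) it was 0.030 with the deposited scaling, 0.12 with median centring, 0.026 with the mean of probe sets, 0.0056 without the arrays numbered 3, and -0.063 to 0.0275 with an array left out, positive without medium array 3. For IL-27 there (-0.02) it was 0.036, 0.16 and 0.017 in the same order, 0.033 with array weights, 0.016 without the arrays numbered 3, and -0.10 to 0.012 with an array left out, positive without medium array 1 or IL-27 array 3. For IL-27 against IL-6 there (-0.01) it was 0.023 with median centring, 0.052 with the mean of probe sets, 0.064 with array weights and 0.0644 without the arrays numbered 3, and -0.017 to 0.0701 with an array left out, positive without IL-6 array 1 or 3 or IL-27 array 1 or 3. In STAT3-deficient cells with IL-6 the naive list moved from -0.13 to 0.027 with median centring, and the co-inhibitory and co-stimulatory list from -0.09 to 0.10 with array weights and to between -0.0888 and 0.15 (without IL-6 array 1) with an array left out. The median of T cell activation genes for IL-27 against IL-6 there was 0.01, against -0.38 with array weights and -0.32 to 0.29 with an array left out. At the preset correlation of 0.01 the list passed the set test as lower without IL-27 array 3 and as higher without IL-6 array 3 or IL-27 array 1. Its estimated correlation was 0.571 and was not used in these fits, so the passes show no direction. For IL-27 in WT cells the median of this list was -0.03, against 0.36 with the covariate and -0.14 (without medium array 1) to 0.19 (without IL-27 array 1) with an array left out. For the genotypes in medium the covariate gave -0.0043 for the antiviral list (0.19), -0.0345 for B cell markers (1.13), -0.0015 for myeloid markers (1.27), -0.22 for H2-Aa and -0.45 for Igha, of which the markers are part of the covariate itself.

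With the larger added constant the changes of weakly expressed genes shrank, for example Plscr1 with IL-6 in WT cells from 3.16 to 1.77 and Tbx21 with IL-27 from 2.03 to 1.33. With the mean of probe sets the IL-6 interaction was -1.45 for Rragd, 1.10 for Sntb1 and 1.22 for Xaf1, all still called.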

Other observations

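Several interferon regulatory factor genes rose with both cytokines and in both genotypes. Genes were grouped into 189 families by the letters before the first digit of their symbol, a grouping chosen after seeing the data. The Irf family so formed can also hold genes that are not interferon regulatory factors. Of its 11 genes, 6 were higher with IL-6 in WT cells (median 0.65) and 6 with IL-27 in WT cells (1.00). In STAT3-deficient cells 5 were higher with IL-6 (0.70) and 6 with IL-27 (1.12). These 4 tests had adjusted p = 0.0171, 0.00398, 0.00121 and 0.00285 with an estimated correlation, and the medians had the same sign with the deposited scaling and with median centring. Irf9, a partner of STAT proteins in the interferon response, rose by 1.40 ± 0.09 and 2.01 ± 0.09 in WT cells and by 1.65 ± 0.09 and 1.63 ± 0.09 in STAT3-deficient cells (IL-6 and IL-27). Irf2 rose by 0.74 ± 0.14, 1.00 ± 0.14, 0.70 ± 0.14 and 1.12 ± 0.14, with IL-6 and IL-27 in WT and then in STAT3-deficient cells, where its IL-6 call was lost in some alternatives (adjusted p up to 0.113). Irf1 and Irf7 had larger IL-6 effects without STAT3, by 0.79 ± 0.13 and 1.29 ± 0.21, while those of Irf2 and Irf9 did not pass (adjusted p = 0.963 and adjusted p = 0.466).

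The Ifi family of 9 interferon-induced genes was higher in 5 with IL-27 in WT cells (median 0.84, adjusted p = 0.0049 with an estimated correlation), 5 with IL-6 in STAT3-deficient cells (0.66, adjusted p = 7.67e-04) and 6 with IL-27 in STAT3-deficient cells (0.85, adjusted p = 0.00285), with the same sign under all 3 scalings.

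Without STAT3, most genes raised by IL-6 were also raised by IL-27. Of the 202 genes raised by IL-6 there, 199 were also raised by IL-27, where 6.6 were expected from independent calls, and none went opposite ways among called genes. That expectation leaves out the shared medium arrays, to which part of the excess may belong. Across genes, which are not independent replicates, the changes correlated with r = 0.80, against 0.50 for simulated changes that shared only the medium arrays, with a covariance of 0.0994 against 0.0314. Of the 202 genes 87 were not called with IL-6 in WT cells, and 61 were in the lists of interferon-inducible GTPases, antiviral genes and MHC class I genes. The IL-27 response was the larger, with 392 genes raised and 46 genes higher with IL-27 than with IL-6. Its slope on the IL-6 change over the called genes was 1.21 (95% interval 1.17 to 1.24, taken over genes and not over arrays).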
